A study of Drosophila melanogaster with 22 samples.

How the data were processed

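The samples were circulating hemocytes (blood cells, called blood here) and lymph glands, the larval blood-forming organs, of Drosophila melanogaster larvae of the wild-type strain Oregon R. Larvae were normal or infested by a parasitoid wasp and were taken 96 h or 120 h after egg laying, which is 24 h or 48 h after infestation. Per the labels' protocols, hemocytes were released from 100 to 150 larvae per condition by vortexing with glass beads, lymph glands were dissected from 10 larvae per replicate, and RNA was taken in TRIzol. Of 22 samples 17 were nanopore cDNA libraries, 16 with the barcoding kit SQK-PCB109 and the 120 h normal lymph gland with another (PCS109). The other 5 were Illumina libraries from a stranded mRNA kit, 1 per condition.

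For each nanopore library the authors deposited whole-number read counts per gene and estimated counts per transcript, which need not be whole, as the values themselves show. Both kinds of table end with lines for ambiguous, unassigned and unaligned reads, which were kept out of library sizes and tests. Ambiguous reads came to 0.498 to 1.29% of the gene counts and reads outside any gene to 0.379 to 0.777%, while 22.3 to 27.9% of the reads were ambiguous between transcripts. For each Illumina library, per the file headers, the authors deposited expected counts, TPM and FPKM per gene and transcript and the percent of its gene that each isoform makes up. TPM and FPKM were not used, and gene expected counts were scaled to the same total in every library (CPM). FastQC 0.11.8, STAR 2.5.3a, StringTie 2.1.3, RSEM 1.3.1 and minimap2 2.17-r941 are named, with no role, per the submitters' processing notes. The genome build, the tool that made the nanopore counts and whether it used strand are not given in the sources used here. Reads of near-identical gene copies and of overlapping or antisense genes may therefore have been divided between them by the authors' counting, and such genes are named as uncertain. Besides annotated genes, the Illumina tables hold 354 unannotated genes of the authors' assembly among 18068 genes. Of 17714 FlyBase gene identifiers 17587 were matched to a symbol in the Ensembl annotation of BDGP6.54, 76 of them through their transcripts, and 127 were not. Coordinates are from that annotation.

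Gene counts as deposited were tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood F test, TMM scaling, Benjamini-Hochberg adjustment, threshold 0.05). All 16 libraries of the SQK-PCB109 kit entered 1 fit with 6 groups, no covariate and 10 residual degrees of freedom, and its common dispersion was 0.0508. Of 13853 genes with a count, 7076 passed filterByExpr (minimum count 10, minimum total 15) and were tested in 7 comparisons: infestation in lymph gland at 96 h, in blood at 96 h and in blood at 120 h, stage in normal blood, tissue in normal larvae at 96 h, and the differences of the infestation effect between tissues and between stages. Log2 fold changes are given with standard errors (SE) and group means as TMM-scaled CPM with SD. A fold against a group without any read is a lower bound, computed against 3 counts over all libraries of that group, and such floors and all intervals cover counting error only.

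Gene lists, 35 in all, were fixed before the data were examined, as were the tests, the comparisons, the rule for naming genes and most of the alternative settings. The lists hold markers of hemocyte classes and of other tissues, immune and other signalling pathways, and metabolic, ribosomal and cell cycle genes. They were tested with camera (limma 3.58.1, correlation preset at 0.01) on log2 CPM with a prior count of 2, again with an estimated correlation, and with fry. Within each list the calls were counted both over all genes tested and adjusted over the list alone, and 14 symbols were matched by an older name. Isoform usage was tested with edgeR's diffSpliceDGE on rounded transcript counts (gene-level F test, with Simes p as the alternative). Shares of counts were compared by exact two-sided permutation tests. Illumina libraries and the 120 h lymph gland, with 1 library per condition, were compared without a test, as log2((CPM + 5) ratio) of genes with at least 100 CPM in the higher library. There a list's median was placed among the medians of 10000 random lists of the same size and expression.

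Named genes were chosen by rule. For each comparison these were the 8 largest rises and the 8 largest falls past the threshold with at least 20 CPM in the higher group and group ranges that did not overlap (no range rule for interactions, and no genes known by an annotation number alone), plus the 4 members of each list with the smallest p. A fixed set of 14 hemocyte markers was added in the infestation and tissue comparisons, and the 6 non-coding or unannotated genes with the smallest p in the infestation comparisons. Isoforms were the 10 genes with the smallest p whose leading isoform's share moved by at least 20 percentage points. Single libraries were described by the 8 largest ratios in each direction.

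The steps were tested with 200 changed genes simulated among the 7076. In lymph gland infestation 28% of 2-fold, 60.6% of 4-fold and 89.8% of 8-fold changes were recovered, and 1.72% of calls were false. Blood gave 15.5, 60.3 and 78.7% at 96 h (2.91% false) and 27.7, 76.2 and 86.1% at 120 h (5.88%). Stage gave 11.2, 56.5 and 67.2% (0%) and tissue 29.4, 63.1 and 70.1% (7.69%). The tissue interaction gave 5.8, 30.5 and 65.3% (5.48%) and the stage interaction 2.82, 38.2 and 52.5% (0%). Most 2-fold differences would be missed. Closeness of blood replicates 2 and 3 was not simulated, so rates involving blood may not hold. Of 1609 genes in the isoform step, swaps of at least 20 points were recovered in 54.3, 62.4, 60.2 and 58.6% of cases for the lymph gland, blood 96 h, blood 120 h and tissue comparisons, and 11.2, 14.7, 12.8 and 13.2% of its calls were false, more than the nominal rate.

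Alternatives were DESeq2 size factors (RLE) and the DESeq2 1.42.0 Wald test, limma voom with sample weights, no or a stricter (20 CPM) filter, only the compared groups, all 17 nanopore libraries, the replicate number as a block, and leaving out each replicate in turn. Chosen after seeing the data were blood replicates 2 and 3 summed or used alone, the removal of genes listed at 0 in a library while well counted in another of its group, and TMM scaling between single libraries. Illumina comparisons of stage and tissue and the shares of ribosomal and mitochondrial RNA were added after seeing the data as well. Correlations of same-numbered replicates' deviations from their group means lay between 0.03 and 0.13 for normal against infested lymph gland and between -0.02 and 0.06 for normal against infested blood, so the numbers were not taken as pairs. Between 96 h and 120 h infested blood all 3 lay above that, at 0.13 to 0.29, and the blocked count is given beside that comparison of stages. No label says that replicates came from separate pools of larvae, and p-values measure only the spread between these samples, which may be technical.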

Results

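Gene expression was measured in larval blood cells with and without infestation by a parasitoid wasp. Larvae respond to this injury by forming lamellocytes, large flat hemocytes that wrap the wasp egg. Other hemocytes are plasmatocytes, which are phagocytic, and crystal cells, which carry the enzymes of melanization. Nanopore libraries covered lymph glands at 96 h (3 normal, 3 infested), blood at 96 h (2 normal, 3 infested) and blood at 120 h (2 normal, 3 infested), with 1 more library of normal lymph glands at 120 h. Gene counts per library lay between 356632 (infested lymph gland replicate 2) and 2079764 (120 h normal blood replicate 2), and the 120 h lymph gland library had 6223590. Between 6915 and 10670 genes were detected in the 16 libraries tested. A count of 0 allowed up to 1.44 to 8.41 CPM per library in these, the highest in the shallowest. Illumina libraries, 1 per condition, covered 96 h infested lymph glands and the 4 blood conditions and held 14750855 to 24307061 expected counts.

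How infestation changed the lymph gland was asked 24 h after the attack, at 96 h. The lamellocyte genes atilla, PPO3 and ItgaPS4 rose from near absence. The surface protein gene atilla (FBgn0032422), the lamellocyte antigen, went from 2.24 ± 3.88 to 583 ± 83.3 CPM (SD, n = 3 each), a log2 fold change of 7.93 ± 0.60 (SE, edgeR adjusted p = 1.84e-06). PPO3 (FBgn0261363), the lamellocyte prophenoloxidase, rose by 7.57 ± 0.57 (edgeR adjusted p = 9.54e-07), to 125 ± 40.4 CPM. ItgaPS4 (FBgn0034005), an integrin alpha subunit, was at least 38.3-fold higher than in normal glands, where it had no reads. Crystal cell genes fell at the same time: PPO1 (FBgn0283437) went from 1072 ± 407 to 73.2 ± 41.7 CPM and PPO2 (FBgn0033367) from 1819 ± 631 to 124 ± 42.2 CPM, both prophenoloxidases (edgeR adjusted p = 6.4e-05 and 4.21e-05).

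Among hemocyte lists in the lymph gland, 9 of 13 lamellocyte markers rose (10 adjusted over the list alone) and none fell (median log2 change 6.72, or 5.26 with genes lacking reads in a group at their bound, camera adjusted p = 3.07e-23). That call held at adjusted p = 0.00274 with an estimated correlation. The tubulin betaTub60D rose by 7.13 on the log2 scale (edgeR adjusted p = 5.05e-08). Of 12 crystal cell markers 9 fell and none rose (10 adjusted over the list alone), with a median of -3.78 or -3.49 at the bounds (camera adjusted p = 4.42e-15, adjusted p = 0.00679 with an estimated correlation). The crystal cell transcription factor lz fell at least 9.38-fold, to no reads. Plasmatocyte markers fell in 7 of 17 cases (12 adjusted over the list alone, median -0.78, camera adjusted p = 2.92e-08, adjusted p = 0.0798 with an estimated correlation). Hml (FBgn0029167), the clotting protein hemolectin, fell from 431 ± 11 to 144 ± 34.1 CPM (edgeR adjusted p = 0.000162) and the peroxidasin Pxn by 1.11 ± 0.24 on the log2 scale (edgeR adjusted p = 0.0115). NimC1, a phagocytic receptor, stood at 120 CPM against 126 (edgeR adjusted p = 0.998). Prohemocyte markers fell in 3 of 8 cases (3 adjusted over the list alone, median -0.61, camera adjusted p = 0.0105, adjusted p = 0.0798 with an estimated correlation). Among them were Tep4, a thioester protein of the medullary zone, by 1.3 ± 0.19, and Ance, a peptidyl dipeptidase, by 1.42 ± 0.21. For the regulators dome, Antp and kn the log2 changes were -0.70, -0.71 and -1.04 and did not pass the test (edgeR adjusted p = 0.701, 0.462 and 0.422). Of 8 posterior signaling centre markers edgeR called none over all genes, 2 had an unadjusted p under 0.05, DESeq2 called 0 and voom 1. Adjusted over the list alone 1 rose and 1 fell, with a list median of -0.81 (camera adjusted p = 0.0236, adjusted p = 0.1 with an estimated correlation).

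Adhesion and cytoskeleton genes of the lymph gland rose in 10 of 30 cases (16 rose and 2 fell adjusted over the list alone, median 0.60, camera adjusted p = 6.67e-09, adjusted p = 0.0227 with an estimated correlation). The integrin subunits ItgaPS5 (2.63 ± 0.29) and mys (1.14 ± 0.16, from 62.2 to 139 CPM) were among them. Extracellular matrix genes fell in 7 of 17 cases and rose in 1 (9 and 1 adjusted over the list alone, median -0.68, camera adjusted p = 4.95e-05, adjusted p = 0.0798 with an estimated correlation). Collagen IV, Col4a1, fell by 1.63 ± 0.19 on the log2 scale. Antimicrobial peptide genes were called as a list with 1 of 11 past the test over all genes, Mtk at 4.83 ± 1.07. Adjusted over the list alone 7 rose (median 3.28, 2.1 at the bounds, camera adjusted p = 0.00357, adjusted p = 0.156 with an estimated correlation). TotA, a Turandot stress peptide, rose by 5.00 ± 0.85 (edgeR adjusted p = 0.00198) and the matrix protease Mmp1 by 2.30 ± 0.30. Notch pathway genes fell in 2 of 13 cases (4 adjusted over the list alone) and heat shock genes in 1 of 16, Hsp23 from 38.7 to 7.05 CPM (3 adjusted over the list alone). Their medians were -0.91 and -1.18 (camera adjusted p = 0.00565 and 0.0105, adjusted p = 0.0909 and 0.287 with an estimated correlation). The ecdysone response, oxidative phosphorylation and ribosomal protein lists were called with medians of -0.60, 0.18 and -0.34 (camera adjusted p = 0.00965, 0.0271 and 4.95e-05). None of these held (adjusted p = 0.156, 0.54 and 0.747 with an estimated correlation). In them edgeR called 0 of 12, 28 and 88 genes, where 4, 2 and 3 had an unadjusted p under 0.05, DESeq2 called 0, 1 and 1 and voom 0, 2 and 0.

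Genes of other organs also differed between normal and infested lymph glands. The serine protease Jon65Aiv, a digestive enzyme, went from 0.307 to 499 ± 393 CPM (log2 change 10.28 ± 1.19, edgeR adjusted p = 6.4e-05). Jon25Bi, yip7, LysS and deltaTry, further digestive enzymes, and the acyl-CoA binding protein Acbp4 were also among the 8 largest rises, with deltaTry at least 137-fold and Acbp4 at least 146-fold higher. Jonah and Lysozyme genes have near-identical copies that the counting may have divided, so single members are uncertain. Of 17 midgut markers 6 rose (6 adjusted over the list alone) and none fell. Their mean log2 change was 3.50, beside a median of 0 because 13 lacked reads in a group (camera adjusted p = 9.37e-05, adjusted p = 0.287 with an estimated correlation). Summed over the list, the 3 infested libraries ranged from 120 to 2151 CPM. Of 18 muscle markers edgeR called 0 over all genes, 14 had an unadjusted p under 0.05, DESeq2 called 0 and voom 1. Adjusted over the list alone 7 fell, and the median was -1.01 (camera adjusted p = 1.44e-06, adjusted p = 0.308 with an estimated correlation). Of 4 heart and pericardial markers 1 fell, the transcription factor Hand by 0.98 on the log2 scale (2 adjusted over the list alone, median -1.20, camera adjusted p = 0.0243, adjusted p = 0.308 with an estimated correlation). No other list was called. Adjusted camera p-values were 0.828 for Toll, 0.691 for Imd, 0.727 for JAK-STAT, 0.32 for JNK, 0.293 for melanization, 0.0778 for phagocytosis, 0.918 for glycolysis, 0.0712 for mitochondrially encoded, 0.471 for cell cycle, 0.616 for histone, 0.946 for insulin and PDGF/VEGF receptor and 0.574 for redox genes. For other tissues they were 0.473 for fat body, 0.727 for cuticle, 0.564 for salivary gland, 0.154 for neuron and glia, 0.757 for ring gland, 0.875 for trachea and 0.616 for male germline markers. Mean and median had opposite signs for the Toll, glycolysis and insulin lists, and the salivary gland median was 0 beside a mean of 0.74.

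In the lymph gland, edgeR called 363 of 7076 genes, 233 higher and 130 lower in infested glands. The groups did not overlap for 352 of them, which is no separate support, since the test itself picks genes whose groups lie apart. Further among the largest changes were mdu, at least 39.3-fold higher, and the aquaporin Drip, at least 39-fold higher. The largest falls included fok (-4.22 ± 0.63), the phosphodiesterase Pde1c (-3.11 ± 0.30), the receptor mthl13, meep, St3 and the transcription factor subunit Taf10b, which was at least 91.5-fold lower. Taf10b is among 193 genes listed at 0 in a library while well counted in another of the same group, and its call was lost when any 1 of the 6 libraries was left out. Leaving out infested replicate 1 gave 199 genes. Calls were lost for Pxn without normal replicate 1 or infested replicate 2 (edgeR adjusted p = 0.0565 and 0.0534), for lz without infested replicate 1 (0.0857) and for Mtk without normal replicate 1 or 2 or infested replicate 1 (0.0625, 0.0627 and 0.0949).

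**Figure D1:**
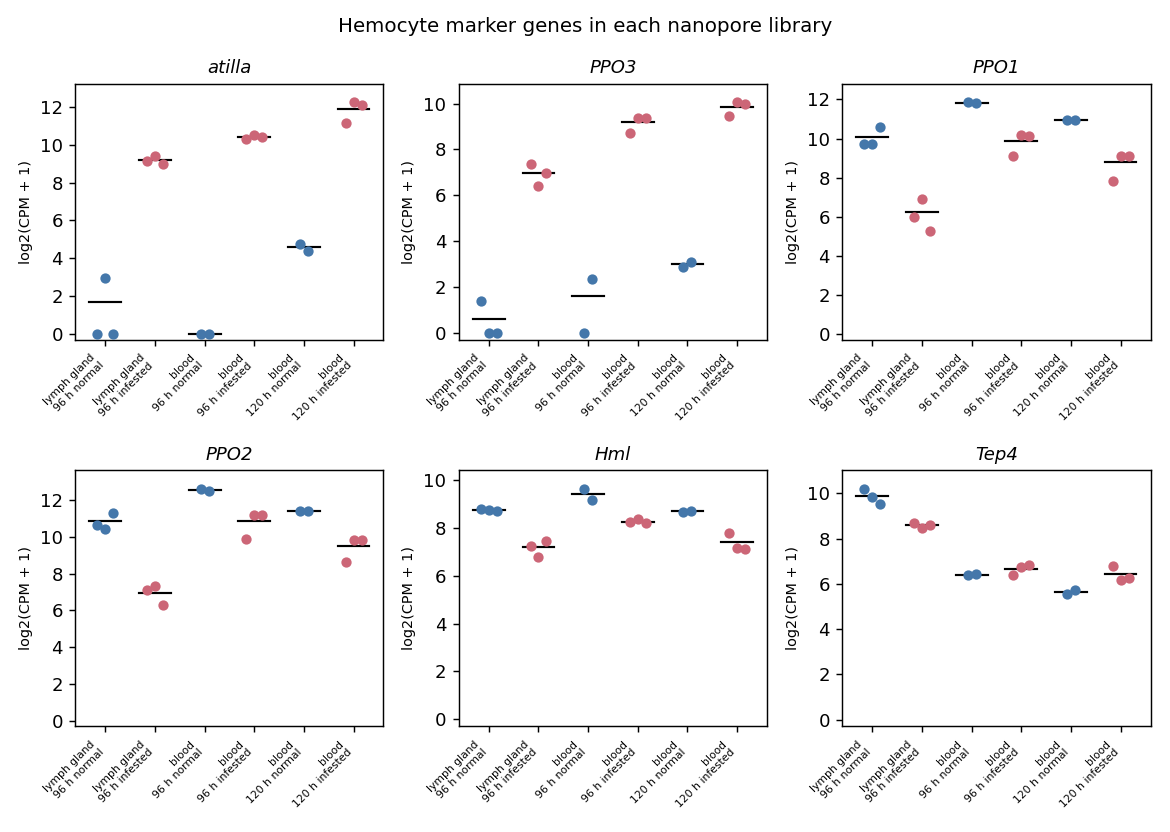
Level of marker genes in each nanopore library, as log2(CPM + 1) on the vertical axis, by tissue, age and condition; each point is a library (blue normal, red infested) and each black line is at the log2 of the group's mean CPM plus 1. In infested lymph glands atilla lies at 583 CPM on average against 2.24 in normal ones, and PPO1 at 73.2 against 1072.

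Blood taken at 96 h, 24 h after infestation, showed the same lamellocyte genes at higher levels. The lamellocyte antigen gene atilla had 1362 ± 84.7 CPM (n = 3) and no reads in 2 normal libraries, at least 577-fold higher (edgeR adjusted p = 4.28e-06). PPO3 went from 1.98 ± 2.80 to 581 ± 142 CPM (log2 change 7.89 ± 0.60) and betaTub60D from 4.59 ± 0.97 to 1425 ± 223 CPM (8.21 ± 0.55), with edgeR adjusted p of 1.1e-06 and 3.79e-07. ItgaPS4 was at least 41.8-fold higher, at 98.6 ± 5.99 CPM against no reads. Crystal cell prophenoloxidases fell, PPO1 by 1.96 ± 0.43 to 938 ± 344 CPM and PPO2 by 1.68 ± 0.41 to 1857 ± 787 CPM (edgeR adjusted p = 0.0159 and 0.0272). Hml fell from 684 ± 158 to 307 ± 20 CPM (edgeR adjusted p = 0.0042).

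In 96 h blood, lamellocyte markers rose in 9 of 13 cases (11 adjusted over the list alone, median 6.28, 5.39 at the bounds, camera adjusted p = 2.58e-21, adjusted p = 0.00391 with an estimated correlation). Crystal cell markers fell in 8 of 12 (10 adjusted over the list alone, median -1.60, camera adjusted p = 4.48e-07, adjusted p = 0.0705 with an estimated correlation). Of 17 plasmatocyte markers 6 fell (8 adjusted over the list alone, median -0.66, camera adjusted p = 0.000836, adjusted p = 0.279 with an estimated correlation), among them Col4a1 from 2335 to 925 CPM and the laminin LanA by 1.03 on the log2 scale. Pxn, NimC1, Tep4 and Ance did not pass, with log2 changes of -0.41, 0.27, 0.26 and 0.67 (edgeR adjusted p = 0.428, 0.578, 0.631 and 0.173). Nor did lz at -2.26 (edgeR adjusted p = 0.105), and Antp had no reads in either group. Integrin and actin genes rose in 11 of 30 (19 adjusted over the list alone, median 0.91, 0.89 at the bounds, camera adjusted p = 1.79e-11, adjusted p = 0.0129 with an estimated correlation), with mys at 2.09 ± 0.20. Extracellular matrix genes fell in 6 of 17 cases and rose in 1 (9 and 2 adjusted over the list alone, median -0.91, -0.75 at the bounds, camera adjusted p = 0.000836, adjusted p = 0.155 with an estimated correlation).

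Immune and metabolic genes of 96 h blood gave smaller counts. In the JAK-STAT list 1 of 13 rose, TotA at 7.89 ± 1.06 (5 rose and 1 fell adjusted over the list alone, median 0.38, camera adjusted p = 0.0386, adjusted p = 0.421 with an estimated correlation). Antimicrobial peptides rose in 2 of 11 (3 adjusted over the list alone, median 2.61, 0.93 at the bounds, camera adjusted p = 0.0184, adjusted p = 0.307 with an estimated correlation), Mtk by 2.89 and AttD at least 6.26-fold. Notch pathway genes fell in 3 of 13, N itself by 1.40 (5 fell and 1 rose adjusted over the list alone, median -1.16, camera adjusted p = 0.00768, adjusted p = 0.153 with an estimated correlation). The glycolysis and trehalose list was not called (camera adjusted p = 0.138), though 3 of its 17 genes rose, the trehalose transporter Tret1-1 by 3.55 ± 0.31, Gapdh2 by 0.89 and Pglym78 by 0.80. Ribosomal protein and mitochondrially encoded genes fell in 2 of 88 and 1 of 24 cases with medians of -0.42 and -0.64 (camera adjusted p = 4.92e-07 and 0.00486, adjusted p = 0.734 and 0.534 with an estimated correlation). In the cell cycle list (median -0.30, camera adjusted p = 0.029, adjusted p = 0.22 with an estimated correlation) edgeR and DESeq2 called 0 of 32 genes, 2 had an unadjusted p under 0.05 and voom called 1.

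Markers of other tissues also moved in 96 h blood. Midgut markers rose in 6 of 17 (12 adjusted over the list alone, median 2.28, 2.22 at the bounds, camera adjusted p = 4.76e-10, adjusted p = 0.141 with an estimated correlation). Jon65Aiv went from 81.4 to 1172 CPM, beside a list sum of 331 ± 27.5 CPM in normal and 3303 ± 1030 in infested blood. Fat body markers rose in 4 of 14 (4 adjusted over the list alone, median 0.63, 0.62 at the bounds, camera adjusted p = 0.0205, adjusted p = 0.47 with an estimated correlation), with the larval serum protein Lsp1alpha at least 42-fold higher (115 against 29.4 CPM in the Illumina libraries). Muscle markers fell in 3 of 18 (8 adjusted over the list alone, median -0.66, camera adjusted p = 3.6e-05, adjusted p = 0.434 with an estimated correlation), for example the giant kinase bt from 581 to 144 CPM. The male germline list had a median of -1.85, -1.29 at the bounds (camera adjusted p = 0.00146, adjusted p = 0.279 with an estimated correlation). Of its 8 genes edgeR called 0, 3 had an unadjusted p under 0.05, DESeq2 called 1 and voom 2.

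At 96 h edgeR called 352 genes in blood, 237 higher and 115 lower. Among the largest rises were also mdu (at least 13.4-fold), the odorant-binding protein Obp99b (at least 133-fold) and the protease Jon25Bii (at least 59-fold). Hexo1 (at least 24.2-fold lower), peb (-2.84 ± 0.64), Strn-Mlck (-2.68 ± 0.47), Pde1c (-2.19 ± 0.23), cpo (-2.14) and St3 (-2.06) fell. Obp99b is among the genes listed at 0 in single libraries. In the Illumina pair the log2 ratios of Obp99b, Hexo1 and Strn-Mlck were 0.76, -0.55 and 0.73, the last with the opposite sign, and normal blood held 5.88 CPM of Obp99b and infested blood 32.7 of Hexo1. In blood, replicates 2 and 3 lay closer to each other than to replicate 1, and with both summed into 1 sample 71 genes were called. That leaves 1 normal sample against 2 infested ones, and the normal one is assumed to vary like the groups that still have replicates, lymph gland and infested blood. Then atilla, PPO3, ItgaPS4, betaTub60D, mys, Tret1-1 and TotA kept their calls and Hml, PPO1, PPO2, Col4a1 and Jon65Aiv did not (edgeR adjusted p = 0.167, 0.271, 0.305, 0.0629 and 0.287). Without normal replicate 2 or 3, 119 or 152 genes were called, and Hml lost its call without the first (edgeR adjusted p = 0.122).

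Blood at 120 h, 48 h after infestation, had the most calls. The lamellocyte genes atilla (3884 ± 1426 CPM against 23.1 ± 4.73, n = 3 and 2), PPO3 (923 ± 201 against 6.96) and ItgaPS4 (491 ± 191 against 4.92) rose by 7.34 ± 0.60, 7.08 ± 0.49 and 6.57 ± 0.46 on the log2 scale (edgeR adjusted p = 1.09e-06, 1.09e-07 and 9.61e-07). The trehalose transporter Tret1-1 rose from 4.92 to 222 CPM (5.42 ± 0.28) and the integrin beta subunit mys from 67.9 to 683 CPM (3.33 ± 0.20). Plasmatocyte and crystal cell genes fell: Hml by 1.31 ± 0.21, Pxn by 1.43 ± 0.25, NimC1 by 0.86 ± 0.21, PPO1 by 2.16 ± 0.44 and PPO2 by 1.86 ± 0.41 (edgeR adjusted p = 0.000473, 0.000959, 0.00925, 0.00252 and 0.00495). Tep4 rose by 0.81 ± 0.24 and Ance fell by 0.78 (edgeR adjusted p = 0.0286 and 0.0324).

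By list, 11 of 13 lamellocyte markers rose in 120 h blood (13 adjusted over the list alone, median 6.16, camera adjusted p = 9.34e-16, adjusted p = 0.00643 with an estimated correlation). Of 30 integrin and actin genes 21 rose (25 adjusted over the list alone, median 1.65, camera adjusted p = 6.39e-14, adjusted p = 0.00643 with an estimated correlation). Crystal cell markers fell in 9 of 12 (11 adjusted over the list alone, median -1.95, camera adjusted p = 3.96e-06, adjusted p = 0.0854 with an estimated correlation). Of 17 plasmatocyte markers 11 fell and 1 rose, the globin glob1 from 30.7 to 186 CPM (13 and 1 adjusted over the list alone, median -1.16, camera adjusted p = 1.33e-05, adjusted p = 0.133 with an estimated correlation). Extracellular matrix genes fell in 10 of 17 and rose in 2 (12 and 2 adjusted over the list alone, median -1.24, -1.16 at the bounds, camera adjusted p = 0.00032, adjusted p = 0.111 with an estimated correlation). Tig stood at -1.83 and Col4a1 at -1.75.

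In the JAK-STAT list of 120 h blood 6 of 13 genes rose and 1, Stat92E, fell (median 1.94, camera adjusted p = 0.0203, adjusted p = 0.306 with an estimated correlation). Those that rose include the cytokine upd3 (3.58 ± 0.71, from 3.33 to 34.9 CPM), TotA (4.36 ± 0.69), the thioester protein Tep2 (3.39) and the phosphatase Ptp61F (1.94). The stress peptides TotM and TotC were at least 68.4-fold and 22.3-fold higher. Members of lists that were not called rose as well. These were 4 of 12 Imd genes (camera adjusted p = 0.244), among them the kinases IKKbeta by 1.87 and Tak1 by 1.29, and 3 of 11 JNK genes (camera adjusted p = 0.129), with Mmp1 going from 34.9 to 146 CPM. In the glycolysis list 5 of 17 rose, Gapdh2 by 1.4 (camera adjusted p = 0.057). Ecdysone response genes were not called as a list (camera adjusted p = 0.185), but 4 of 12 fell and 1 rose, the hormone receptor EcR by 1.65 and the transcription factor br from 93.8 to 19.3 CPM among the falls. Heat shock genes fell in 6 of 16 (7 adjusted over the list alone, median -1.01, camera adjusted p = 0.000414, adjusted p = 0.149 with an estimated correlation), with Hsp23 from 1351 to 143 CPM (-3.23 ± 0.30). Cell cycle genes fell in 4 of 32, PCNA by 0.57 and E2f1 by 1.17 (2 adjusted over the list alone, median -0.43, camera adjusted p = 0.00138, adjusted p = 0.0854 with an estimated correlation). Ribosomal protein and mitochondrially encoded genes had medians of -0.52 and -0.54 (camera adjusted p = 1.02e-06 and 0.0351, adjusted p = 0.567 and 0.547 with an estimated correlation). Of 88 ribosomal protein genes 1 rose and 1 fell. Of 24 mitochondrial genes edgeR and DESeq2 called 0, 2 had an unadjusted p under 0.05 and voom called 2. In the phagocytosis list 6 of 19 rose and 4 fell, eater by 2.01, with median -0.28, mean 0.31 and camera adjusted p = 0.915. Melanization genes had 2 of 7 rising and 3 falling, with median -0.56, mean 0.24 and camera adjusted p = 0.528.

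Among other tissues at 120 h, midgut markers fell in 14 of 17 (14 adjusted over the list alone, median -3.63, -3.43 at the bounds, camera adjusted p = 4.64e-09, adjusted p = 0.111 with an estimated correlation). Among them yip7 went from 120 to 1.41 CPM and Jon25Bi from 86.6 to 1.63. In the Illumina pair of that age the midgut sum was higher in infested blood, at 41.9 against 14.07 CPM. By edgeR all 8 male germline markers rose, where voom called 8 and DESeq2 3 (8 adjusted over the list alone, median 2.11, camera adjusted p = 1.33e-05, adjusted p = 0.111 with an estimated correlation), including ocn from 23.6 to 118 CPM and the sperm chromatin protein ProtB by 2.44. Of the 11 list genes that could be compared between the single Illumina libraries of these conditions, 9 were at least 2-fold lower in infested blood. Fat body markers fell in 3 of 14, apolpp by 1.65 and Lsp2 by 1.38 (3 adjusted over the list alone, median -1.07, camera adjusted p = 0.011, adjusted p = 0.413 with an estimated correlation). Their sum was 5501 CPM in infested replicate 1, above the 3911 and 4487 of the normal libraries, and 1079 and 1137 in the other 2. Leaving out normal replicate 2 or normal replicate 3 alone took the calls of apolpp and Lsp2 away.

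For 120 h blood edgeR called 1375 genes, 799 higher and 576 lower in infested larvae. The largest rises also held Ocho (at least 55.3-fold), Myo28B1 (at least 43.3-fold), the fibroblast growth factor pyr (at least 28.2-fold), Npc2b, the adenosine receptor AdoR and Epac, and the largest falls the homeotic gene Ubx (at least 101-fold lower), sPLA2, LysB, deltaTry, Jon25Biii and Jon99Cii. Ubx, sPLA2, LysB and Jon99Cii are among the genes listed at 0 in single libraries. With replicates 2 and 3 summed, again 1 normal sample with the spread taken from other groups, 435 genes were called. Then atilla, PPO3, ItgaPS4, mys, Tret1-1, TotA, Hml, Hsp23 and yip7 kept their calls and PPO1, PPO2, Pxn, NimC1, upd3, ocn and ProtB did not (edgeR adjusted p = 0.0687 to 0.22). Without normal replicate 2 or 3, 616 or 735 genes were called, and NimC1, upd3, ProtB, TotM or EcR lost their calls without 1 of them.

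**Figure D2:**
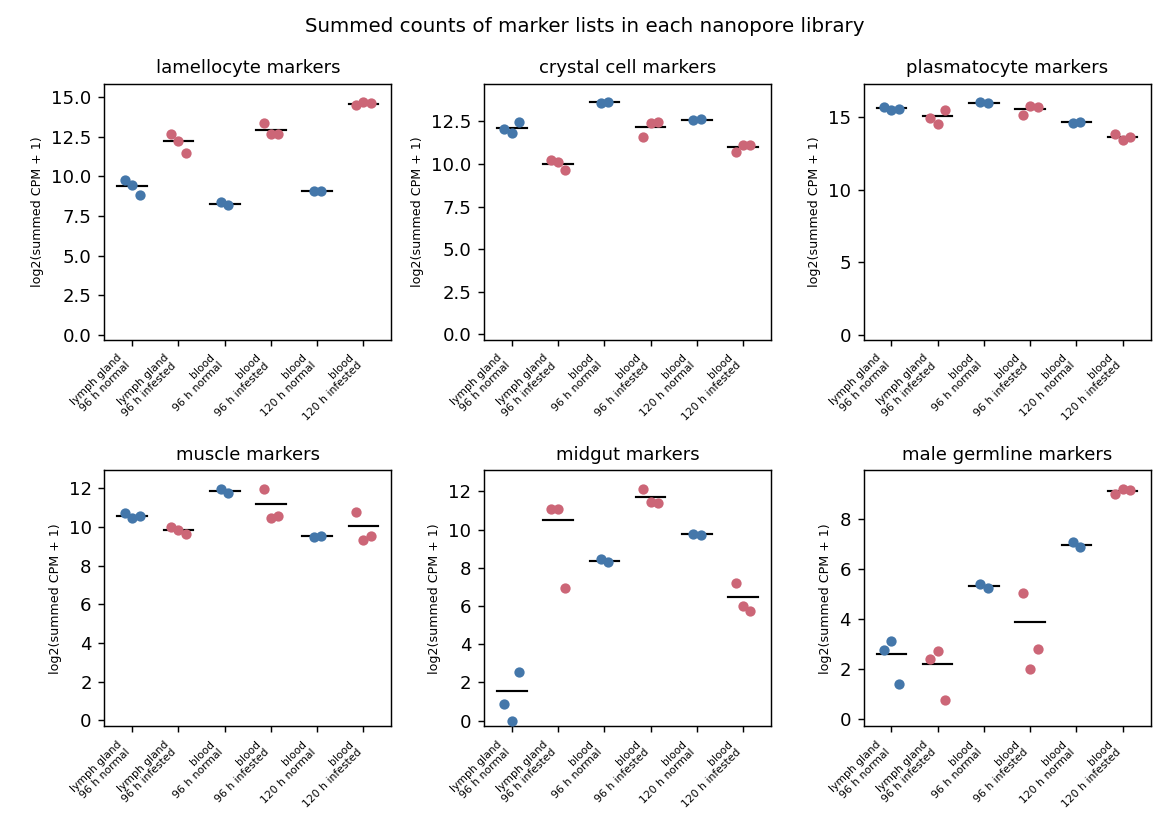
Summed level of 6 marker lists in each nanopore library, as log2(summed CPM + 1) on the vertical axis, by tissue, age and condition; points are libraries (blue normal, red infested) and black lines the log2 of the group's mean plus 1. Lamellocyte sums average 4707 CPM against 670 in lymph glands and 24420 against 540 in 120 h blood, while midgut sums in the infested lymph glands spread from 120 to 2151 CPM.

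Across the infestation comparisons many calls coincided. Lymph gland and 96 h blood, which share no library, had 126 genes higher in both (7.8 if independent), 43 lower in both (2.11 if independent) and 2 with opposite directions. With 120 h blood the lymph gland shared 166 higher (26.3 if independent) and 74 lower (10.6 if independent) with 19 opposite, and the 2 blood ages shared 180 higher (26.8 if independent) and 60 lower (9.36 if independent) with 15 opposite. All 3 comparisons had 109 genes higher, among them atilla, PPO3, ItgaPS4, ItgaPS5, Itgbn, mys, betaTub60D, Drip, mdu, Tret1-1, Mmp1, TotA, the lamin LamC and yellow-f. All 3 had 36 lower, among them PPO1, PPO2, Hml, Col4a1, LanA, LanB1, eater, Tig, Glt, Men, peb, Pde1c and St3.

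Non-coding genes were part of this shared response. The long non-coding RNA lncRNA:CR44948 (FBgn0266253, chromosome 3R, 25496078 to 25496478, minus strand) lies apart from other genes. It rose by 6.68 ± 0.45 in lymph glands, to 301 CPM, by 7.86 ± 0.54 in 96 h blood, to 1502 CPM, and by 7.03 ± 0.46 in 120 h blood, to 5597 ± 1149 CPM (edgeR adjusted p = 2.46e-07, 4.28e-07 and 6.25e-08). CR44316 (2R, 12320594 to 12320912, minus strand) rose by 2.80 ± 0.32, 5.78 and 5.41, and marge (3L, 14976626 to 14977631, minus strand) by 4.44 ± 0.52, 6.21 and 5.29. The antisense RNA CR42738 (3R, 7143487 to 7144295, plus strand), rose by 7.07 ± 0.80, 5.72 and 7.52, but it overlaps CG14610 on the opposite strand and reads of the pair may not have been told apart. The same holds for atilla (2L, 12175451 to 12177886, minus strand), which lies opposite part of bru1. Of unannotated genes of the authors' assembly 2 rose in all 3 comparisons and 1 fell, and the foremost rose by 2.37, 3.10 and 6.31, in 120 h blood from 4.12 to 321 CPM (edgeR adjusted p = 2.49e-08). In the other direction lncRNA:CR45660 fell in all 3 comparisons, in 96 h blood from 88.5 to 20.3 CPM (edgeR adjusted p = 0.000279), but it overlaps Pxn on the same strand.

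Shares of counts in whole RNA classes were compared by exact permutation tests, which in these group sizes cannot go below p = 0.1. Transcripts of the authors' non-coding class took 0.0722% of counts in normal and 0.19% in infested lymph glands, 0.0334% and 0.292% in 96 h blood, and 0.0599% and 0.862% in 120 h blood (exact two-sided p = 0.1 each, 0.262 after adjustment over 21 tests). In all 3 comparisons every infested library lay above every normal one. Annotated long non-coding RNAs took 1.1 ± 0.03% in normal and 1.59 ± 0.17% in infested 96 h blood (exact p = 0.1) and 1.53% and 2.27% at 120 h (exact p = 0.2). In lymph glands they stood at 1.58% and 1.5% (exact p = 1). CR44948 and CR44316, 25.7 and 10.2% of long non-coding counts in infested 120 h blood, carried the rise there. With CR34335 (7371 to 9657 CPM) they carried that at 96 h.

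Stage was compared in normal blood, 120 h against 96 h, with 2 libraries each. The larval serum protein gene Lsp2 went from 9.49 to 391 CPM (5.35 ± 0.71), Lsp1alpha was at least 137-fold higher at 323 ± 48.8 CPM (154 against 29.4 CPM in the Illumina libraries), and Hsp23 went from 84.3 to 1351 CPM (4.02 ± 0.38, edgeR adjusted p = 1.73e-05). Myosin heavy chain, Mhc, went from 238 to 7.39 CPM (-4.55 ± 0.92, edgeR adjusted p = 0.00972) and Act57B from 406 to 57.8 CPM, and the cuticle protein Lcp65Ag1 was at least 88.6-fold lower. Ecdysone response genes br (29.4 to 93.8 CPM) and EcR (1.76) rose (edgeR adjusted p = 0.0185 and 0.0404).

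By list, 12 of 18 muscle markers fell with stage (17 adjusted over the list alone, median -2.44, camera adjusted p = 5.12e-16, adjusted p = 0.157 with an estimated correlation). So did 6 of 14 cuticle markers (8 adjusted over the list alone, median -4.23, -2.90 at the bounds, camera adjusted p = 8.72e-09, adjusted p = 0.157 with an estimated correlation). Fat body markers rose in 5 of 14 (7 rose and 1 fell adjusted over the list alone, median 2.28, 1.78 at the bounds, camera adjusted p = 0.00155, adjusted p = 0.301 with an estimated correlation). Midgut markers rose in 3 of 17 (6 adjusted over the list alone, median 1.16, camera adjusted p = 0.00123, adjusted p = 0.341 with an estimated correlation). Heat shock genes rose in 3 of 16 (median 0.90, 0.61 at the bounds, camera adjusted p = 0.00645, adjusted p = 0.301 with an estimated correlation). Lamellocyte markers rose in 4 of 13 (5 adjusted over the list alone, median 1.63, 1.06 at the bounds, camera adjusted p = 0.000242, adjusted p = 0.157 with an estimated correlation), with betaTub60D at 4.72 and atilla at least 9.77-fold higher at 23.1 CPM. Crystal cell markers fell in 2 of 12 (median -0.89), and plasmatocyte markers fell in 5 and rose in 1 of 17 (median -0.31), papilin, Ppn, going from 652 to 161 CPM (camera adjusted p = 0.0022 and 0.00222, adjusted p = 0.256 and 0.301 with an estimated correlation). Oxidative phosphorylation genes fell in 2 of 28 and Notch genes in 1 of 13 cases, with medians of -0.22 and -1.26 (camera adjusted p = 0.000277 and 0.00685, adjusted p = 0.301 and 0.157 with an estimated correlation). The mitochondrially encoded, glycolysis and cell cycle lists had medians of -0.53, -0.42 and -0.26 (camera adjusted p = 0.0319, 0.0278 and 0.00345, adjusted p = 0.657, 0.347 and 0.157 with an estimated correlation). In these edgeR and DESeq2 called 0 of 24, 17 and 32 genes, 3, 4 and 3 had an unadjusted p under 0.05 and voom called 2, 2 and 1. Antimicrobial peptide genes rose in 1 of 11 cases, Drs by 2.70 (list median 2.7, 0.6 at the bounds, camera adjusted p = 0.0355, adjusted p = 0.341 with an estimated correlation). Salivary gland and male germline markers had medians of 7.11, 3.27 at the bounds, and 2.03 (camera adjusted p = 0.0262 and 7.75e-05, adjusted p = 0.52 and 0.157 with an estimated correlation). Of 8 genes in each, edgeR and DESeq2 called 0, 1 and 5 had an unadjusted p under 0.05 and voom called 6 and 3. For the matrix list the median was -0.30 and the mean 0.03 (4 of 17 fell, 1 rose, camera adjusted p = 0.0391, adjusted p = 0.341 with an estimated correlation).

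With stage 302 genes were called by edgeR, 159 higher and 143 lower at 120 h. Obp99b, Hsp26, Ubx and MsrA were among the largest rises and frm (at least 42.3-fold lower), Lcp65Ae, Cpr67Fa1, Lcp65Ac and loh (-5.90 ± 0.56) among the largest falls. Obp99b, Hsp26, Ubx, MsrA and Lcp65Ag1 are listed at 0 in single libraries, and Lcp65Ag1 has a near-identical copy. In the Illumina pair frm had the opposite sign, at 5.14 CPM at 120 h and 0.735 at 96 h, and Lcp65Ae, Cpr67Fa1 and Lcp65Ac stood under 1 CPM at both ages. All 4 libraries were replicates 2 and 3, so with each pair summed either age is 1 sample and all spread comes from lymph gland and infested blood. Then 26 genes were called, and Lsp2, Mhc and Act57B were not (edgeR adjusted p = 0.0807, 0.151 and 0.0626). Leaving out 96 h replicate 2 or 3 or 120 h replicate 2 or 3 gave 131, 138, 114 or 142 genes.

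Tissue was compared in normal larvae at 96 h, blood (n = 2) against lymph gland (n = 3). Plasmatocyte genes were higher in blood, NimC1 at 677 CPM against 126 (2.43 ± 0.22, edgeR adjusted p = 5.26e-06), Col4a1 at 2335 against 566 and Pxn at 888 against 360 (1.3, edgeR adjusted p = 0.004). Crystal cell PPO1 and PPO2 were higher by 1.77 ± 0.43 and 1.71 ± 0.41 (edgeR adjusted p = 0.0192 and 0.0173), whereas Hml, at 684 against 431 CPM, did not pass (edgeR adjusted p = 0.0731). Lower in blood were the prohemocyte genes Ance (118 against 1969 CPM, -4.06 ± 0.29) and Tep4 (83.8 against 951 CPM, -3.50 ± 0.25, edgeR adjusted p = 5.21e-07 for both), and the transcription factors Antp and kn, at least 7.41-fold and 7.34-fold. The steroid synthesis genes spok and phtm, expressed in the neighbouring ring gland, were at least 31.1-fold and 20.6-fold lower in blood.

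In the lists, 12 of 17 plasmatocyte markers were higher in blood (14 adjusted over the list alone, median 1.21, camera adjusted p = 4.75e-10, adjusted p = 0.0468 with an estimated correlation). So were 12 of 17 extracellular matrix genes, with 2 lower (12 and 3 adjusted over the list alone, median 1.3, camera adjusted p = 9.53e-06, adjusted p = 0.0523 with an estimated correlation). Crystal cell markers were higher in 5 of 12 cases (9 higher and 1 lower adjusted over the list alone, median 1.49, camera adjusted p = 0.000367, adjusted p = 0.126 with an estimated correlation). Melanization genes were higher in 4 of 7 (6 adjusted over the list alone, median 1.65, camera adjusted p = 0.000323, adjusted p = 0.0523 with an estimated correlation). Posterior signaling centre markers were lower in 5 of 8 (median -6.64, -2.25 at the bounds, camera adjusted p = 1.78e-06, adjusted p = 0.00577 with an estimated correlation). Prohemocyte markers were lower in 2 and higher in 1 of 8 (median -1.37, camera adjusted p = 0.00722, adjusted p = 0.0523 with an estimated correlation). Of ring gland markers 4 of 6 were lower (5 adjusted over the list alone, median -5.70, -2.71 at the bounds, camera adjusted p = 1.44e-09, adjusted p = 0.00224 with an estimated correlation), with the adipokinetic hormone Akh at 2.61 against 55.6 CPM. Heart and pericardial markers were lower in 2 of 4, Hand at 2.93 against 99.1 CPM (median -2.84, camera adjusted p = 0.000899, adjusted p = 0.148 with an estimated correlation). Higher in blood were 8 of 14 cuticle (median 4.06, 3.35 at the bounds), 9 of 17 midgut (6.62, 4.08 at the bounds) and 4 of 18 muscle markers (0.97), with camera adjusted p of 4.32e-10, 8.77e-11 and 0.000278 (adjusted p = 0.0347, 0.0523 and 0.407 with an estimated correlation). Mitochondrially encoded genes, male germline markers and histones had medians of 0.76, 3.32 and -1.59, the last 2 being 1.87 and -1.43 at the bounds (camera adjusted p = 0.00139, 0.000702 and 0.00788, adjusted p = 0.407, 0.185 and 0.23 with an estimated correlation). In them edgeR called 0 of 24, 8 and 5 genes, 5, 4 and 4 had an unadjusted p under 0.05, DESeq2 called 0, 2 and 1 and voom 8, 1 and 3.

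Between the tissues edgeR called 531 genes, 338 higher and 193 lower in blood. Cuticle genes Vajk3 (at least 78.6-fold), Cpr60D (at least 57.4-fold) and obst-E (at least 35-fold) were among the most raised, and odd, sog, mthl13, mthl7 and veil were at least 9.37-fold lower. With blood replicates 2 and 3 summed, 1 blood sample without a spread of its own stood against 3 of lymph gland. Then 215 genes were called, NimC1, Col4a1, Ance, Tep4, Antp, spok and phtm among them, and Pxn, PPO1, PPO2 and kn were not (edgeR adjusted p = 0.0535 to 0.182). Without blood replicate 2 or 3, 301 or 269 genes were called.

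**Figure D3:**
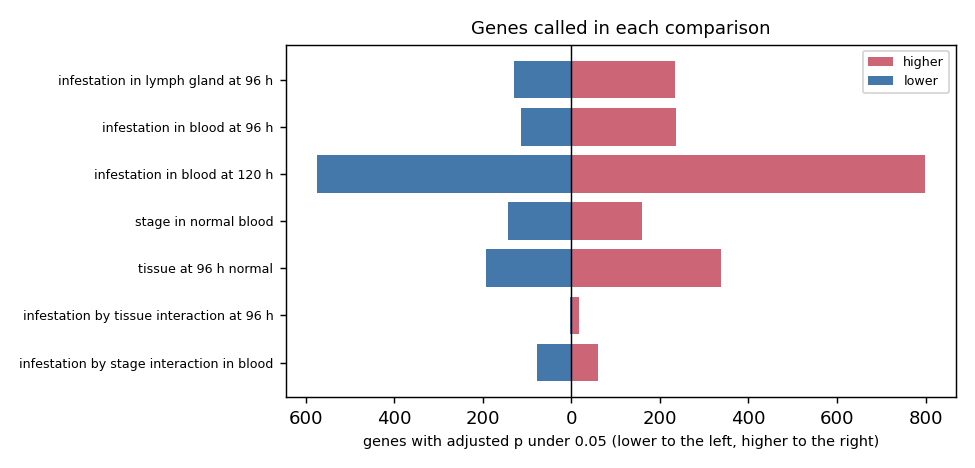
Number of genes called by edgeR at an adjusted p under 0.05 in each of the 7 comparisons, split on the horizontal axis by direction (first-named group higher or lower). Infestation in 120 h blood has 799 higher and 576 lower genes, and the tissue difference of the infestation effect 17 and 3.

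Whether infestation acted differently in blood and lymph gland at 96 h was tested as an interaction, which gave 20 genes, 17 of them higher in blood relative to lymph gland. Ance, with 118 and 188 CPM in normal and infested blood and 1970 and 737 CPM in lymph glands, differed by 2.09 ± 0.34, and Tep4 by 1.56 ± 0.31 (edgeR adjusted p = 0.0171 and 0.0465). The glutathione transferase GstD3 rose from 124 to 319 CPM in blood and went from 474 to 332 CPM in lymph glands (difference 1.87 ± 0.30, edgeR adjusted p = 0.0171). Arc1 rose from 60.3 to 416 CPM in lymph glands and was at 271 and 275 CPM in blood (-2.74 ± 0.45, edgeR adjusted p = 0.018). Each of these 4 lost its call without at least 2 of the 11 libraries. Crystal cell markers fell less in blood, with 2 of 12 called (6 adjusted over the list alone, median difference 2.12, 1.5 over the 10 with reads in all 4 groups, camera adjusted p = 0.00107, adjusted p = 0.349 with an estimated correlation). With blood replicates 2 and 3 summed, normal blood again being 1 sample, 1 gene was called. Leaving out single libraries gave 4 and 5 (blood normal replicates 2 and 3), 32 and 12 (blood infested 1 and 3), and 8, 10 and 34 genes (lymph gland infested 1, 2 and 3).

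Between stages the infestation effect in blood differed for 137 genes, 59 more positive and 78 more negative at 120 h (70 and 69 with RLE scaling). Stage cannot be told apart from time since attack. The digestive enzymes yip7, Jon25Bi and Jon65Aiv rose at 96 h and fell at 120 h, with differences of -9.95 ± 1.40, -9.46 ± 1.29 and -7.81 ± 1.13 (edgeR adjusted p = 0.00221, 0.00198 and 0.00278). In the Illumina pair at 120 h all 3 stood higher in infested blood, yip7 and Jon25Bi under 2 CPM and Jon65Aiv at 5.7 against 0.247 CPM. The male germline gene ocn went from 9.14 to 1.74 CPM at 96 h and from 23.6 to 118 CPM at 120 h (4.55 ± 1.00, edgeR adjusted p = 0.0375). Troponin C TpnC73F rose from 27.5 to 205 CPM at 120 h against 92.6 and 78.6 CPM at 96 h (3.18 ± 0.55), and metallothionein MtnA from 103 to 422 CPM at 120 h against 571 and 379 CPM at 96 h (2.60 ± 0.35, edgeR adjusted p = 0.00807 and 0.00198). When each of the 10 libraries was left out in turn, yip7, Jon25Bi, Jon65Aiv and MtnA kept their calls, and ocn lost its call without 8 of them and TpnC73F without 2. The integrin and actin list was more positive at 120 h (2 of 30 called, median 0.56, camera adjusted p = 0.000154, adjusted p = 0.191 with an estimated correlation). With the replicate number as a block 217 genes were called, and with replicates 2 and 3 summed, 1 normal sample per age, edgeR called 0, where 619 had an unadjusted p under 0.05, DESeq2 called 16 and voom 3. Leaving out single libraries gave 61 and 26 (96 h normal replicates 2 and 3), 76 and 88 (96 h infested 2 and 3), 23 and 60 (120 h normal 2 and 3), and 246, 63 and 85 genes (120 h infested 1, 2 and 3).

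Isoform usage was compared in 1609 genes with 4067 transcripts. Targ2 changed in all 3 infestation comparisons. Its transcript FBtr0078312 made up 100% of the gene's counts in normal and 56 ± 1.07% in infested lymph glands (diffSpliceDGE adjusted p = 0.000272), 100% and 39.7 ± 7.88% in 96 h blood (adjusted p = 0.00328), and 89.1 ± 2.55% and 32.5 ± 6.11% in 120 h blood (adjusted p = 0.000442). The Illumina tables gave 85.5 and 35.6% for normal and infested blood at 96 h and 56.3 and 26.8% at 120 h. In 120 h blood the leading transcript of ics went from 100 to 12.6 ± 3.52% (adjusted p = 1.35e-05), that of the GTPase regulator RapGAP1 from 100 to 5.7 ± 5.05% and that of the adhesion protein CAP from 81.2 ± 26.5 to 13.5 ± 4.45%. In lymph glands wun, a lipid phosphatase, went from 100 to 51.2 ± 11.9% (adjusted p = 0.000166). Between normal tissues cu, the clock-related nocturnin, differed with 91 ± 4.91% in blood and 52.2 ± 4.98% in lymph gland (adjusted p = 0.00157). In all, 6 genes were called in lymph glands, 20 in 96 h blood, 27 in 120 h blood and 13 between tissues, and Simes p gave 3, 2, 11 and 4. Many of these genes had few counts (5 to 26 per library for wun), and in 6, 12, 13 and 7 of the calls an isoform had no counts in a group. Without lymph gland normal replicate 1 or 2 or infested replicate 3 the first count was 10, 10 or 2. Without 96 h normal replicate 2 or 3 or infested replicate 1 or 3 the second was 6, 31, 9 or 9, and without lymph gland normal replicate 2 or blood replicate 3 the last was 22 or 35.

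Illumina libraries, 1 per condition and so without a replicate check, gave the same leading genes at 96 h. In infested against normal blood betaTub60D stood at 4860 against 32.2 CPM (log2 ratio 7.03), ItgaPS4 at 1106 against 5.27 (6.76), PPO3 at 1046 against 9.98 (6.13) and atilla at 563 against 4.78 (5.86), while PPO1 stood at 4166 against 25420 (-2.61). The lamellocyte list had a median of 5.32 and the crystal cell list one of -2.44, at percentiles 100 and 0 among random lists. Of genes called by edgeR in the nanopore libraries, 92% had the same direction in the Illumina pair at 96 h (320 of 348, exact 95% interval 88.6 to 94.6), 66.8% at 120 h (902 of 1350, 64.2 to 69.3) and 87.4% for stage (250 of 286, 83 to 91). If the platforms were independent these shares would be 54.2, 48.7 and 50.6%. At 96 h the share was 99.6% for higher and 75.7% for lower genes, and over all genes the Spearman correlation of the changes was 0.47 at 96 h, 0.08 at 120 h and 0.44 for stage. Among the genes chosen by rule and called, 3 of 62 had the opposite sign at 96 h, 31 of 108 at 120 h and 6 of 58 for stage. Of the bounds given against groups without nanopore reads, 7 of 9, 11 of 11 and 12 of 14 lay above the Illumina ratio, computed with 5 CPM added to both libraries. At 120 h the Illumina lamellocyte median was 5.00 and atilla had a log2 ratio of 6.23, but Hml stood at 7491 against 916 CPM (3.02), opposite to its nanopore fall. Opposite as well were Col4a1 (5363 against 2540 CPM), Pxn (0.79), PCNA (1.70), the cell cycle list (median 1.07, percentile 100, 27 of 32 positive) and the male germline and mitochondrially encoded lists (-2.29 and 0.44), while plasmatocyte markers had a median of -0.03. For stage the midgut list (median -1.89, 0 of 5 positive) and the cuticle list (1.99, 4 of 4 positive) were opposite, and at 96 h the muscle list (0.49, percentile 100, 16 of 18 positive). These are 3 of 12, 2 of 16 and 1 of 13 called lists with an Illumina value. All 120 h and stage values of this platform rest in part on the normal 120 h library. Its gap between transcript and effective length was 162.2 bases against 213.4 to 230.1 in the others, and its levels had the lowest correlation with the nanopore ones (Spearman 0.62 against 0.71 to 0.78). Between stages in normal blood, Hml was at 916 CPM at 120 h against 21180 at 96 h (-4.52). Among the genes furthest above infested lymph gland in infested blood was Hsp70Ab, at a log2 ratio of 4.85, and spok and phtm, listed at 0 in blood, had 125 and 101 CPM in the gland. Scaling between libraries changed the balance of 2-fold differences at 120 h, from 325 higher and 385 lower to 469 and 308, and for stage from 514 and 261 to 367 and 424, as it moved the log2 ratios by 0.328 and -0.404.

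Lymph gland at 120 h, a single library of another kit, was set beside the 96 h normal mean, so age and kit cannot be told apart. Antimicrobial peptide genes stood higher, Mtkl at 611 against 96.0 CPM (log2 ratio 2.61) and Dro at 2.40. Ribosomal protein genes had a median of 0.42 (percentile 100) and muscle markers one of -1.31 (percentile 0). Tep4 stood at 256 against 899 CPM (-1.79) and atilla had a log2 ratio of 1.19. With library totals 24 genes were at least 2-fold higher and 66 lower, and with TMM scaling, which moved the log2 ratios by 0.349, 58 and 30.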

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

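The tests of replicate closeness, midgut RNA, testis RNA and male germline genes between platforms were chosen after the results were seen. The test of male larvae and the regroupings of lymph gland libraries were set beforehand.

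Infestation effects differed between tissues at 96 h, by a test of the difference itself, for 20 genes. Among those with a more positive effect in blood, GILT3 (difference 2.3, log2 changes 1.36 in blood and -0.94 in lymph gland), Ance (2.09) and SppL (1.95) fell in the gland without a fall in blood. GstD3 (1.87), CAP (1.79, with 1.89 in blood), Erasp (1.76, with 1.79 in blood) and cib (1.1, with 1.51 in blood) rose in blood, and Tep4 differed by 1.56. Arc1 (-2.74) and EndoG (-1.95, from 13.4 to 25.5 CPM in the gland) were larger in the gland. Each of these 10 genes lost its call without at least 2 of the 11 libraries, CAP, Tep4 and cib without 9.

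By list, the tissues differed for lamellocyte (median difference 0.95, camera adjusted p = 0.000782), crystal cell (2.12, adjusted p = 0.00107), posterior signaling centre (1.23, adjusted p = 0.00107), melanization (0.48, adjusted p = 0.0365), phagocytosis (0.51, adjusted p = 0.0387) and male germline genes (-0.87, adjusted p = 0.0088). None held with an estimated correlation (adjusted p = 0.349, 0.349, 0.0816, 0.444, 0.467 and 0.444), where 3 of 35 lists had an unadjusted p under 0.05 and fry called 5. Of the 8 signaling centre genes 2 had reads in all 4 groups (median 0.41), and of the 8 male germline genes none had. Over all genes edgeR called 1 of 13 lamellocyte, 2 of 12 crystal cell and 1 of 19 phagocytosis genes. In the signaling centre, melanization and male germline lists it called 0, where 1, 2 and 0 had an unadjusted p under 0.05, DESeq2 called 0, 1 and 0 and voom 0, 1 and 0.

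The infestation effect in blood also differed between 96 h and 120 h, for 137 genes. More positive at 120 h were the male germline genes Mst84Da (7.98, a fitted value with no reads in 96 h infested blood), Dpy-30L2 (6.14), Mst87F (5.01) and ocn (4.55), and TpnC73F (3.18), rgn (3.1), CAP (2.61) and MtnA (2.6). More negative were Lsp1alpha (-10.84, a fitted value with no reads in 96 h normal blood) and the digestive enzymes yip7 (-9.95), Jon25Bi (-9.46), Phae1 (-9.05), Jon65Aiv (-7.81), LysB (-7.73), Jon65Aiii (-7.21) and deltaTry (-6.84). Leaving out each of the 10 libraries in turn ended no call of yip7, Jon25Bi, Jon65Aiv, Jon65Aiii and MtnA, while Mst84Da, Dpy-30L2, Mst87F, ocn and Lsp1alpha each lost theirs without 8 libraries and LysB without all 10.

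Lists that differed between stages were midgut (median -6.35, or -5.5 over 15 genes with reads in all groups, 11 of 17 called), fat body (-2.22, or -1.37 over 10) and heat shock genes (-1.26, or -0.9 over 14), and with a positive sign male germline (4.08, or 3.56 over 6), muscle (0.8) and integrin and actin genes (0.56). Camera gave adjusted p = 1.58e-21, 2.39e-05, 0.00186, 1.61e-09, 0.0281 and 0.000154. With an estimated correlation these were adjusted p = 0.0516, 0.308, 0.341, 0.0684, 0.776 and 0.191, so none held, 5 lists had an unadjusted p under 0.05 and fry called 7.

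Blood replicates 2 and 3 lay close together. In the 4 groups their biological coefficient of variation (BCV) was 0.0837 to 0.118, against 0.256 to 0.315 for pairs with replicate 1, so the closest such pair stood 2.2 times as far apart as the widest pair of replicates 2 and 3. Depth does not account for this, since BCV allows for counting noise and stayed at or under 0.118 over the same depths. A candidate explanation is that replicates 2 and 3 share a source, such as a pool of larvae or a preparation, that replicate 1 does not. The labels name no such source, so it stays open, and with it how far p-values of the blood comparisons reach beyond that source.

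Midgut digestive enzyme genes rose in infested lymph glands, Jon65Aiv to 499 ± 393 and LysS to 288 ± 234 CPM from under 1, and the summed list varied 17.9-fold among the 3 infested libraries, against 2.28-fold for the lamellocyte list. Such a spread is consistent with midgut RNA carried over in amounts that differ between dissections. A rise with infestation in hemocytes at both times cannot be told apart from it, since at 120 h the list median was -3.63 in nanopore libraries but the summed list was higher in the single infested Illumina library (41.9 against 14.07 CPM). Midgut transcripts in the mix of the blood libraries would give 124 CPM of Jon99 genes in infested replicate 1, where no counts were found (limit 2.11 CPM), though some genes, Jon99Cii among them, are listed at 0 in single libraries for reasons not known. A response to infestation at 96 h alone stays open as untested.

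Male germline genes, all 8 with reads in normal 120 h blood too, rose in infested blood of that age with a list median of 2.11, ocn to 118 and Mst87F to 104 CPM. The sum of the male-specific roX RNAs differed less, at 322 ± 71.3 CPM (n = 3) against 238 ± 23.3 (n = 2), a log2 ratio of 0.44. Neither roX2 nor roX1 passed the test (edgeR adjusted p = 0.216 and 0.487). The smaller roX difference argues against more male larvae as the whole of the germline rise. Some excess of males in the infested samples is not excluded by it. Infested over normal, the germline sum had a ratio of 4.02 in nanopore and 0.164 in Illumina libraries, a 24.6-fold gap that testis RNA carried over in differing amounts may explain. Whether infestation itself raises these genes cannot be told apart from that, as the Illumina median of -2.29 rests on a single library per condition, of which the normal one stands apart.

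Regrouping the 6 lymph gland libraries in all 10 ways gives too few splits for a share under 0.05. For genes 1 split, the real one, gave as many (363, highest other 1). The same held for lists, with 1 split (16, highest other 8), and for isoform usage, with 1 split (6, highest other 4).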

How the results depend on the processing

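Chosen after the data were seen were blood replicates 2 and 3 summed or alone and removal of genes listed at 0 in single libraries. So were leaving out libraries in the list tests and TMM between single libraries. The other settings were planned.

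Counts of called genes stayed within 1.5 times the values of the report for all 7 comparisons with DESeq2's size factors (RLE), with all 17 nanopore libraries, with a mean of at least 20 CPM and without the genes listed at 0 in single libraries. RLE moved the median by at most 0.07 on the log2 scale. The totals of 2-fold genes in the single-library comparisons also stayed within that range with an offset of 1 CPM and with TMM, although TMM turned the balance of higher and lower genes for Illumina infestation at 120 h, Illumina stage and the 120 h lymph gland (there from 24 higher and 66 lower to 58 and 30).

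Other settings moved counts, and the cause was not tested unless given. DESeq2 called 61 genes for the tissue interaction. With voom and quality weights there were 603 for 96 h blood, 2276 for 120 h blood, 721 for stage, 951 for tissue, 54 for the tissue interaction and 834 for the stage interaction. With no low-count filter there were 636 for lymph gland, 744 for 96 h blood, 660 for stage, 893 for tissue, 183 for the tissue interaction and 488 for the stage interaction. Fits of the compared groups only gave 222 for lymph gland, 726 for stage and 10 for the tissue interaction. With the replicate number as a block there were 454 for stage, 32 for the tissue interaction and 217 for the stage interaction, and 14 isoform calls in lymph gland and 26 between tissues. The number pairs normal libraries of lymph gland and of 120 h blood with infested ones better than other pairings, but not those of 96 h blood. Summing replicates 2 and 3, which leaves 1 sample in each normal blood group and takes the spread from the others, gave 71 genes for 96 h blood, 435 for 120 h blood, 26 for stage, 215 for tissue, 1 for the tissue interaction and 0 for the stage interaction (edgeR, where 619 had an unadjusted p under 0.05, DESeq2 called 16 and voom 3). Replicates 2 and 3 alone gave 461 for stage, 58 for the tissue interaction and 300 for the stage interaction.

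Lists depended most on the correlation between genes. With an estimated one 3 lists were called in lymph gland, 2 in 96 h blood, 2 in 120 h blood and 4 between tissues, and 0 for stage and both interactions (camera, where 6, 3 and 5 had an unadjusted p under 0.05 and fry called 17, 5 and 7). In 120 h blood fry called 20. Isoform calls by Simes p were 3, 2, 11 and 4 for lymph gland, 96 h blood, 120 h blood and tissue, and a stricter transcript filter, which tests fewer, gave 8 between tissues. The share of genes called by DESeq2 with the same direction in Illumina at 120 h was 73.6%.

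Without single libraries in turn, genes called ran from 199 (without infested replicate 1) to 419 for lymph gland, 119 (without normal replicate 2) to 279 for 96 h blood, 616 (without normal replicate 2) to 1289 for 120 h blood, 114 (without 120 h replicate 2) to 142 for stage, 269 (without blood replicate 3) to 529 for tissue, 4 (without blood normal replicate 2) to 34 (without lymph gland infested replicate 3) for the tissue interaction and 23 (without 120 h normal replicate 2) to 246 (without 120 h infested replicate 1) for the stage interaction. Lists ran from 13 to 17, 12 to 16, 13 to 15, 11 to 15, 14 to 19, 4 to 12 and 5 to 9 in the same order. Isoform calls ran from 2 to 10 for lymph gland, 6 to 31 for 96 h blood, 22 to 31 for 120 h blood and 13 to 35 for tissue. A lone normal blood library is then assumed to vary like the other groups.

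Of the values of named genes without 1 library, 5789 kept direction and side of the threshold, 654 lost their call, 56 gained one and 2 reversed. With replicates 2 and 3 summed 640 stayed and 231 lost their call, with DESeq2 937 stayed, 32 lost and 41 gained it, and with voom 883 stayed, 7 lost and 128 gained it. The tallies include genes not called, which cannot lose a call and dilute the losses. Sgs8 and Sgs3 reversed in 120 h blood, not called at 1.44 and 0.91 (edgeR adjusted p = 0.62 and 0.72). Sgs8 is listed at 0 in infested replicate 3, where another replicate predicts 205 counts. The salivary gland sum ran from 24.71 to 899.6 CPM among infested 120 h libraries, so that may rest on 1 high library. Their log2 changes were -4.11 and -2.62 with voom, -4.77 and -2.92 with the block, -5.38 and -2.97 with replicates 2 and 3 alone, and without single libraries they ran from -5.38 and -2.95 (without infested replicate 1) to 2.05 and 1.52.

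Depth limits what a count of 0 means, up to 8.41 CPM in the shallowest nanopore library, and single Illumina libraries allow no test.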

Other observations

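Chosen after the data were seen was the comparison of zero counts with Illumina libraries.

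Single genes of lists not called also rose in infested 120 h blood. The PDGF/VEGF-like factor Pvf2 rose by 2.90 ± 0.63 (edgeR adjusted p = 0.0047), the fibroblast growth factor receptor btl by 3.52 ± 0.77 (edgeR adjusted p = 0.00538), the tumour necrosis factor egr by 3.17 ± 0.84 (edgeR adjusted p = 0.0154) and the Toll adaptor Myd88 by 1.48 ± 0.34 (edgeR adjusted p = 0.00677). All 4 lost their calls without normal replicate 2 (edgeR adjusted p = 0.106, 0.103, 0.0698 and 0.111), egr also without normal replicate 3 (0.0848). The serpin Spn27A fell by 1.61 ± 0.24, from 555 to 182 CPM, and the glutathione transferase GstE1 from 205 to 109 CPM (edgeR adjusted p = 0.000193 and 0.00175), and both kept their calls without each library. In the Illumina pair GstE1 had the opposite sign (55.2 against 18.7 CPM). Of 15 redox and iron genes 1 rose and 5 fell (camera adjusted p = 0.057).

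Single genes of lists not called between normal blood and lymph gland at 96 h also differed, where tissue and way of collection again cannot be told apart. Higher in blood were Hsp70Ab (42.8 against 1.97 CPM) and thioredoxin Trx2, by 1.12 ± 0.18 (edgeR adjusted p = 2.4e-05 and 0.000769). Lower in blood were GstD1 (1561 against 3542 CPM), the translation repressor Thor by 1.71 ± 0.32, the receptor Tl by 1.33 ± 0.27 and PGRP-LB by 2.33 ± 0.56 on the log2 scale (edgeR adjusted p = 0.000221, 0.00328, 0.0061 and 0.0186). Without blood replicate 2 calls were lost for Thor, Tl and PGRP-LB (edgeR adjusted p = 0.0507, 0.052 and 0.143), and without blood replicate 3 for Tl and PGRP-LB (0.0843 and 0.105).

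Ribosomal RNA took 3.32 ± 0.55% of counts in normal and 0.944 ± 0.63% in infested 96 h blood (1.67, 0.542 and 0.624% in replicates 1, 2 and 3), and unannotated genes 1.33% and 0.4% (exact p = 0.1 and 0.262 adjusted, both). At 120 h the shares were 1.06% and 1.13%, and 0.481% and 0.494% (exact p = 1 and 0.9). Transcripts with an alternative end of known genes took 4.03% in normal and 5.19% in infested 120 h blood (exact p = 0.1). In normal lymph glands lncRNA:CR34335 alone made up 44.9% of long non-coding counts.

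In 193 genes, 182 of them tested, a nanopore library listed 0 counts where the highest other replicate of its group predicted at least 20. There were 307 such zeros in all and 4 to 33 per library. A single high replicate can also give such a zero. For 242 of these zeros an Illumina library of the same condition exists, and in it 202 (83.5%) had at least 5 CPM and 4 (1.65%) had none. The male germline sum of the Illumina library of 120 h normal blood was 1337 CPM against 218.8 in the infested library of that age.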
